A study of Mus musculus with 14 samples.

How the data were processed

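DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads cytosines near restriction sites, mostly in CpG-rich DNA, in 10 libraries. RNA was measured by sequencing in 4 libraries. All came from mouse tail fibroblasts labelled wildtype or AID-null. AID, activation-induced deaminase, is a cytosine deaminase. Each genotype had 1 RRBS and 1 RNA library of untreated fibroblasts, and 1 of each from cells 3 weeks into reprogramming with Oct4, Sox2, Klf4 and cMyc. Each genotype also had 3 RRBS libraries of clones picked at 2 weeks and measured after 3 weeks. Groups were taken from the sample titles.

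Per the submitters' processing notes, Bismark, methylKit, TopHat and Cufflinks were used with the mouse build mm9. Tool versions, trimming, filters and the gene annotation were not given in the sources used here. The deposited RRBS files list, per the file headers, the coverage of each CpG cytosine on each strand as a read count, together with the percent of reads that were methylated (C) and converted (T). Every listed position had a coverage of at least 10. The 2 percent columns summed to under 100 in 1.65% to 5.99% of positions, and the remaining reads were not used here. The deposited RNA files give FPKM per gene (fragments per kilobase of transcript, scaled to the mapped fragments of the library), a unit normalised by the authors. FPKM summed to 1708869 to 2012350 per library. Low FPKM values shared no common step between libraries, so the RNA read depth is unknown and no count model was used for RNA.

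Methylated and unmethylated reads were recovered from coverage and percent. Positions above the 99.9th percentile of coverage in a library, 683 to 983 reads, were left out. Reads were summed over 1000 bp tiles with at least 3 positions covered in every library compared. Autosomes were used unless X or Y is named. The 3 AID-null clones were compared with the 3 wildtype clones by a quasi-binomial model per tile on 113450 tiles. Its dispersion was moderated across tiles with limma 3.58.1 in R 4.3.3, with a trend on the binomial information and a floor of 1. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 25 percentage points. On simulated tiles for this comparison, the model without the trend recovered 8% of 40-point and 33% of 60-point differences. The trend was added after that test, and the model then recovered 69% and 99%. Of 170 simulated calls 2 were false, and 0 tiles were called in simulated data with no difference. The simulated tiles had the median spread of tiles of like methylation, were drawn independently and had no shift of a whole clone. These rates therefore need not hold for the real clones, and 0 calls there do not exclude differences of such sizes. The tools limma on log2 ratios, edgeR 4.0.16 and Fisher's exact test on pooled reads were run as alternatives.

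Values per clone were compared by exact two-sided permutation of 3 against 3, for which 0.1 is the smallest possible p. The labels do not say whether clones came from separate animals or cultures, so these p-values measure the spread between these clones. Single libraries were compared by Fisher's exact test per tile over 108306 tiles covered in all 10 libraries, called at the same adjusted p and 25 points. That test compares the libraries and not the conditions, and picked clones give no measure of the spread between bulk cultures. Methylation levels per library were taken over 1304324 autosomal positions covered in all 10 libraries, with 193017753 to 232251940 reads each. The 95% Wilson interval of such a level was at most 0.0066 points to each side. On X, with 2044790 to 4444315 reads, it was at most 0.064 points. Intervals cover counting error only, since RRBS reads carry no molecular identifiers here.

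RNA differences were taken on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was counted as higher or lower at a difference of at least 1, among genes with at least 1 FPKM in either library. With 1 library per group there was no test and no p-value. The 21 gene lists were written from textbook markers, and each list's median is given with its percentile among 10000 random lists of the same size matched on mean expression. Among lists of genes drawn at random from the same libraries, 99% of those shifted by 1 lay above the 97.5th percentile. Of unshifted ones 3.5% lay outside the 2.5th to 97.5th percentile, a low rate that follows from the drawing. Random lists draw genes independently, whereas the genes of a marker list can vary together. A percentile therefore gives a list's place among such draws and is not a p-value. Of 22026 gene symbols 99.1% matched the gene table, whose assembly is GRCm38.p6. Of 330 list genes 329 were found, 3 of them by an older symbol. That table differs from mm9 in build, so it was used for names and gene order alone. Promoter methylation was not analysed here.

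Groups, tests, thresholds, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a later choice is stated. For RNA the rule takes, in each contrast, the 10 genes highest and the 10 lowest on the log2 scale with at least 5 FPKM in either library. It adds the 4 members of each list that differ most, and in all cases a fixed set with Pou5f1, Sox2, Klf4, Myc and Nanog. An item of that set is not reported here. For RRBS it takes up to 10 called tiles each way. The text gives those that a comparison rests on. Alternatives varied the coverage minimum, coverage limit, tile size, positions per tile, chromosomes, thresholds, test, centring, pseudocount, filter on low values and RNA scaling, and left out each clone in turn. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and matplotlib 3.10.9 for figures.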

Results

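DNA methylation was profiled in 10 libraries and RNA in 4 libraries from mouse tail fibroblasts labelled wildtype or AID-null. The untreated fibroblasts and the 3-week reprogrammed cultures were each represented by 1 RRBS library and 1 RNA library per genotype, without replicates. The reprogrammed clones were represented by 3 RRBS libraries per genotype. Total coverage summed over CpG positions was 231642626 in wildtype fibroblasts, 222945430 in AID-null fibroblasts, 263448576 in the wildtype 3-week culture and 295179206 in the AID-null 3-week culture. It was 283839215, 279665786 and 287780746 in wildtype clones 1 to 3 and 236887310, 229745779 and 296572452 in AID-null clones 1 to 3. The libraries covered 1659832 to 2154007 positions each at a median coverage of 82 to 125. Mitochondrial positions, a measure of incomplete conversion, read 0.0832% to 0.143% methylated. The RNA libraries listed 13381 genes with at least 1 FPKM in wildtype fibroblasts and 13589 in AID-null fibroblasts. They listed 14668 such genes in the wildtype and 14537 in the AID-null 3-week culture.

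All groups are named by their labels. The libraries of the 2 genotypes differed in sex-linked genes. The Y-linked translation factor gene Eif2s3y was listed at 0 in both libraries labelled wildtype, and at 184 FPKM in fibroblasts and 274 FPKM at 3 weeks under the AID-null label. Xist, the RNA that coats the inactive X chromosome, was listed at 456 and 149 FPKM under the wildtype label and at 0.99 and 1.78 FPKM under the AID-null label. Over the 5 sex-linked genes the median log2 difference was 5.54 in fibroblasts and 5.82 at 3 weeks. The 5 RRBS libraries labelled AID-null covered 506 to 648 positions on Y, and the 5 labelled wildtype covered 27 to 48. X took 1.03% to 1.14% of coverage in the former and 1.95% to 2.09% in the latter. Every comparison of genotypes below is therefore also a comparison between cells with and without Y sequence.

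The comparison of untreated fibroblasts asked how the genotypes differed before reprogramming. Macrophage genes were higher in the fibroblast library labelled AID-null. Of 16 measured members 13 were at least 2-fold higher and 0 were lower, with a median log2 difference of 1.67 (percentile 100 of random lists). Fcer1g, a signalling subunit of immune receptors, stood at 51.9 FPKM in the wildtype and 225 FPKM in the AID-null library, and the complement gene C1qc at 30.5 and 120 FPKM. Muscle genes had a median difference of 1.39 with 6 of 10 members at least 2-fold higher, among them the myosin light chain gene Mylpf at 2.28 and 10.6 FPKM. Others of them had low values, such as Actc1 at 0 and 2.78 FPKM and Myh3 at 0.22 and 2.02 FPKM. Cell cycle genes had a median difference of 0.73 (percentile 100), and 2 of 22 members were at least 2-fold higher, Ccna2, which encodes cyclin A2, at 35.6 and 79.9 FPKM and the proliferation marker Mki67 at 23.7 and 51.3 FPKM. Senescence and p53 genes had a median of −0.32 (percentile 0), with 0 of 13 members beyond 2-fold. Cdkn1a, the p53 target that blocks the cell cycle, stood at 1206 FPKM in the wildtype and 651 FPKM in the AID-null library. The keratin genes Krt8, Krt18 and Krt19 were listed at 0 in the wildtype library and at 28.1, 34.1 and 29.5 FPKM in the AID-null library. Imprinted Mest stood at 108 and 342 FPKM. Fibroblast and mesenchymal genes differed little in size, with a median difference of 0.08 and 1 of 32 members beyond 2-fold, although that median lay at percentile 100 of random lists. DNA methylation and demethylation genes had a median of 0.21, with the maintenance factor Uhrf1 at 16.8 and 28.1 FPKM. In all, 588 genes were at least 2-fold higher and 185 at least 2-fold lower under the AID-null label, of 13788 compared. Over 22026 genes the log values of the libraries correlated at r = 0.992, and genes are not independent replicates.

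Reprogramming was compared with the starting fibroblasts within each genotype. Pluripotency genes were far higher at 3 weeks in both genotypes. Pou5f1, which encodes Oct4, was 9.49 higher on the log2 scale in the wildtype and 8.88 higher in the AID-null culture, a value that does not separate delivered from endogenous transcripts. Nanog, a pluripotency regulator that was not among the delivered factors, went from 1.29 to 347 FPKM in the wildtype and from 0 to 265 FPKM in the AID-null libraries. Dppa5a, a marker of pluripotent cells, went from 2.24 to 3160 FPKM and from 4.29 to 3264 FPKM. Of 40 secondary pluripotency genes 39 were at least 2-fold higher in the wildtype, with a median of 6.99, and 38 in the AID-null comparison, with a median of 5.85. All 20 epithelial genes were at least 2-fold higher in both, with medians of 5.50 and 4.90. The epithelial adhesion gene Cdh1 went from 0.41 to 296 FPKM in the wildtype and from 4.67 to 289 FPKM in the AID-null libraries.

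Other groups moved together in both genotypes at 3 weeks. Cell cycle genes had medians of 3.32 in the wildtype and 2.33 in the AID-null comparison, and DNA methylation genes 1.75 and 1.39, with the de novo methyltransferase gene Dnmt3b going from 3.2 to 389 FPKM and from 4.78 to 193 FPKM. Germline genes known to depend on promoter methylation had medians of 2.22 and 2.93, and primitive endoderm and trophoblast genes 2.38 and 1.77. Fibroblast genes were lower, by a median of −3.03 in the wildtype with 28 of 32 members at least 2-fold lower, and by −1.71 in the AID-null comparison with 21 of 32. Collagen gene Col1a1 stood at 0.604% of its fibroblast level in the wildtype culture and at 3.71% in the AID-null culture. Interferon response genes had medians of −1.06 and −1.03, cartilage and bone genes −1.73 and −1.04, and macrophage genes −3.10 and −1.96. In the wildtype comparison 4098 genes were higher and 2693 lower, and in the AID-null comparison 3208 and 2652. Genes higher in both numbered 2440, where independent lists would share 841, and genes lower in both 1640, where they would share 457.

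The comparison of 3-week cultures asked whether expression at this stage differed with the genotype label. Secondary pluripotency genes were lower in the library labelled AID-null. Their median log2 difference was −0.79 (percentile 0.01), and 17 of 40 members were at least 2-fold lower and 2, Dppa3 and Spp1, higher. The nuclear receptor gene Nr0b1 stood at 332 FPKM in the wildtype and 26.8 FPKM in the AID-null library. Threonine dehydrogenase Tdh, a metabolic enzyme of pluripotent cells, stood at 274 and 55.8 FPKM, Lin28b, an inhibitor of let-7 microRNA processing, at 15.2 and 2.28 FPKM, and Klf2, a pluripotency transcription factor, at 238 and 51.2 FPKM. Dppa5a, Fbxo15, Fgf4 and Tdgf1 of the same list differed by 0.05, 0.05, 0.10 and 0.16. The reprogramming factor genes had a median of −0.81, with Pou5f1 at −0.63, Sox2 at −0.63, Klf4 at −1.28 and Myc at −0.99. Nanog differed by −0.39, and the 3 core pluripotency genes had a median of −0.63 (percentile 14.5).

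Fibroblast genes were higher at 3 weeks in the library labelled AID-null, by a median of 1.51 (percentile 100), with 20 of 32 members at least 2-fold higher and 0 lower. Col6a1 and Lum, which encode extracellular matrix proteins, stood at 51.3 and 29.2 FPKM in the wildtype and at 968 and 545 FPKM in the AID-null library. The matrix gene Thbs4 was 7.03 higher on the log2 scale, at 3395 FPKM, and Rarres2, which encodes the chemokine-like protein chemerin, stood at 1.91 and 923 FPKM. Macrophage genes had a median of 2.67 with 11 of 16 members at least 2-fold higher, including Tyrobp, an immune receptor adaptor listed at 0 in the wildtype and at 48.2 FPKM in the AID-null library. Germline genes had a median of 0.59 (percentile 98.9), with 7 of 18 members at least 2-fold higher, 1 lower and 10 between. The piRNA pathway gene Mael stood at 15.1 and 73.7 FPKM and the germ cell gene Dazl at 14.4 and 64.1 FPKM. Piwil2 and Tex19.1 of the same list went the other way, at 47.6 and 19.9 FPKM and at 140 and 70.1 FPKM. Keratinocyte genes had a median of −1.59 (percentile 0). Krt6a and Krt6b, keratins of stressed epidermis, stood at 33.3 and 96.2 FPKM in the wildtype and were listed at 0 in the AID-null library. Primed and mesendoderm genes had a median of −1.11, with the transcription factor gene Pou3f1 at −1.56, while Otx2 of the same list stood at 168 and 343 FPKM. Several lower members of the keratinocyte and primed lists had low values. Ivl stood at 3.09 FPKM and Wnt3 at 1.16 FPKM in the wildtype, and both were listed at 0 in the AID-null library. DNA methylation genes had a median of −0.24, within the range of random lists, with Dnmt3b at 389 and 193 FPKM and Apex1, a base excision repair enzyme, at 606 and 209 FPKM.

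At 3 weeks 1484 genes were at least 2-fold higher and 1757 at least 2-fold lower in the library labelled AID-null, of 15204 compared. The median gene differed by −0.18, and by 0.0021 after upper-quartile scaling and 0.02 after median-of-ratios scaling. The counts were then 1880 higher and 1233 lower, or 1926 and 1197, so the balance of directions depended on the scaling. Without genes on X and Y the counts were 1434 and 1592. The medians of the secondary pluripotency, fibroblast, macrophage, germline, keratinocyte and primed lists kept their signs under both scalings. Of the genes at least 2-fold higher under the AID-null label in both states there were 171, where independent lists would share 41.8, and 51 were lower in both, where 12.8 would be shared.

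**Figure D1:**
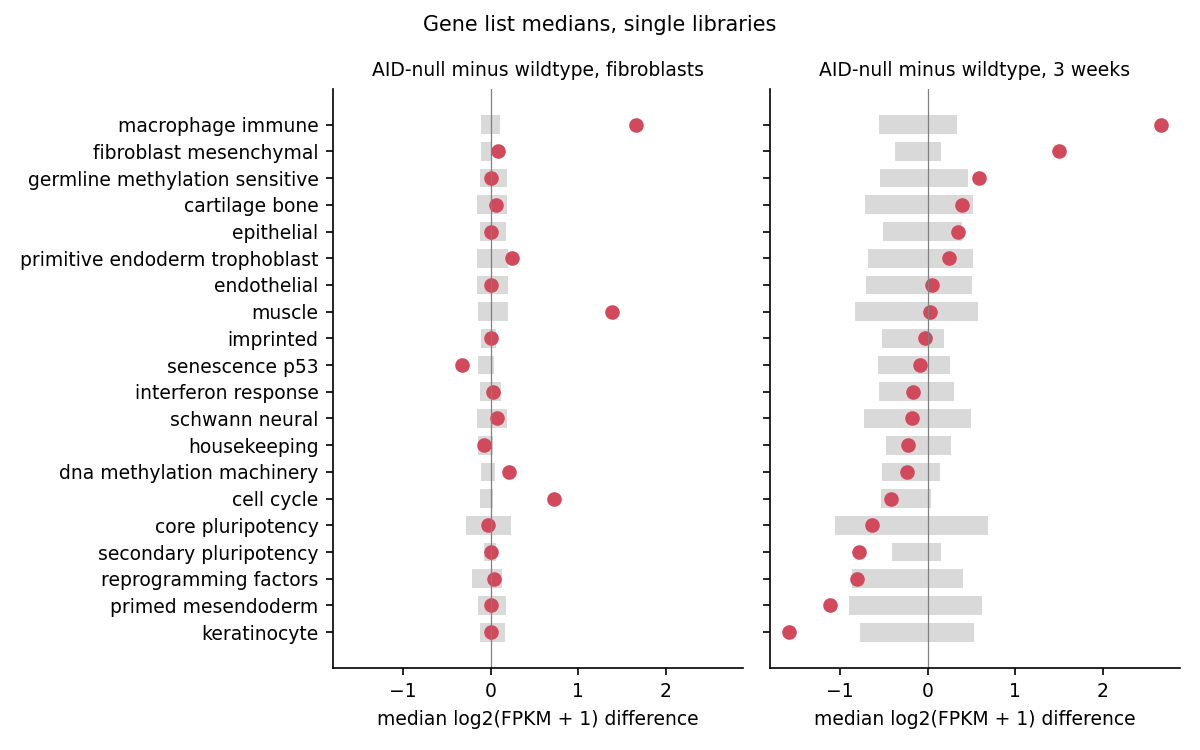
Median log2(FPKM + 1) difference of each gene list, AID-null minus wildtype, in fibroblasts and at 3 weeks, with grey bars for the mean of 10000 matched random lists plus and minus 2 SD (1 library per group; the sex-linked list is left out). At 3 weeks the secondary pluripotency median was −0.79, the fibroblast median 1.51 and the macrophage median 2.67.

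The reprogramming changes of the genotypes were then set against each other, AID-null minus wildtype. Secondary pluripotency genes had a median difference of −1.07 with 22 of 40 members at least 2-fold lower, and cell cycle genes a median of −1.07 with 13 of 22 lower. Between the 3-week cultures alone the cell cycle median was −0.41 (percentile 12.2), with 1 of 22 members at least 2-fold lower, against 0.73 between the fibroblasts. Fibroblast genes had a median of 1.48 with 22 of 32 members higher. Uhrf1, which was lower at 3 weeks and higher in fibroblasts under the AID-null label, had a difference of −1.51, and Trp53, which encodes p53, −1.26. Keratinocyte and muscle genes had medians of −1.25 and −1.21, and neural and Schwann cell genes −1.01. The muscle median was 1.39 between the fibroblasts and 0.03 between the 3-week cultures, so that difference lay mainly in the fibroblasts. There were 1513 genes with a difference of at least 1 and 2173 with a difference of at most −1. After upper-quartile scaling the numbers were 1832 and 1701, and after median-of-ratios scaling 1902 and 1625. These differences had no replicate check.

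Methylation of the fibroblast libraries was compared to ask whether the genotypes differed at the start. Over 108306 autosomal tiles mean methylation was 55.6% in wildtype and 54.9% in AID-null fibroblasts. Methylated reads ran the other way, at 29.0% and 31.9% of reads over shared positions. Tiles at least 25 points higher under the AID-null label numbered 398, and 645 were lower, by Fisher's exact test between these libraries. Picked clones of the same genotype differed in 2981 to 14802 tiles, which is no measure of the spread between bulk cultures. With X and Y kept, 1210 tiles were lower. X-linked positions read 51.8% methylated in wildtype and 39.0% in AID-null fibroblasts.

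Loss of methylation during reprogramming was compared within each genotype. In the wildtype culture 33998 tiles were at least 25 points lower at 3 weeks than in fibroblasts and 2446 were higher. In the AID-null culture 11249 tiles were lower and 2533 higher. Mean tile methylation went from 55.6% to 40.9% in the wildtype and from 54.9% to 47.9% in the AID-null libraries. Pooled over shared positions, methylated reads went from 29.0% to 23.5% and from 31.9% to 25.2%, so by this measure the AID-null change, −6.77 points, was larger than the wildtype change, −5.50 points. The mean of positions went from 32.5% to 23.5% and from 32.1% to 27.6%, so the direction of the contrast between genotypes depended on the weighting by reads. Of the tiles lower in the AID-null culture 89.7% were also lower in the wildtype culture, and 10092 tiles were lower in both, where independent sets would share 3531. The 3531 is taken over all tiles, among them 23021 that stayed below 10% and could not be 25 points lower. It is therefore too low a baseline. The tiles lower in the wildtype culture had a mean difference of −36.1 points there and −19.9 points in the AID-null culture. X-linked positions went from 51.8% to 30.7% in the wildtype and from 39.0% to 30.6% in the AID-null libraries.

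The 3-week cultures were compared to ask whether methylation persisted under the AID-null label. Over tiles the library labelled AID-null was more methylated, with 2449 at least 25 points higher and 60 lower. Tiles whose clone mean lay at least 25 points below the fibroblast mean averaged 53.6% in the AID-null and 43.0% in the wildtype culture (18645 tiles). Tiles above 60% in fibroblasts and clones, with less than 10 points between the means, averaged 75.2% and 64.6% (18477 tiles). Tiles at least 25 points higher in clones than in fibroblasts averaged 46.9% and 45.9% (6135 tiles), and tiles that stayed below 10% averaged 1.40% and 1.46% (23021 tiles). These tile classes were chosen after the difference was seen. Positions at or above 80% methylation made up 10.4% of shared positions in the AID-null and 2.75% in the wildtype culture. In all 2509 tiles differed, against 1043 between the fibroblast libraries, and no replicate culture gave the spread between cultures.

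**Figure D2:**
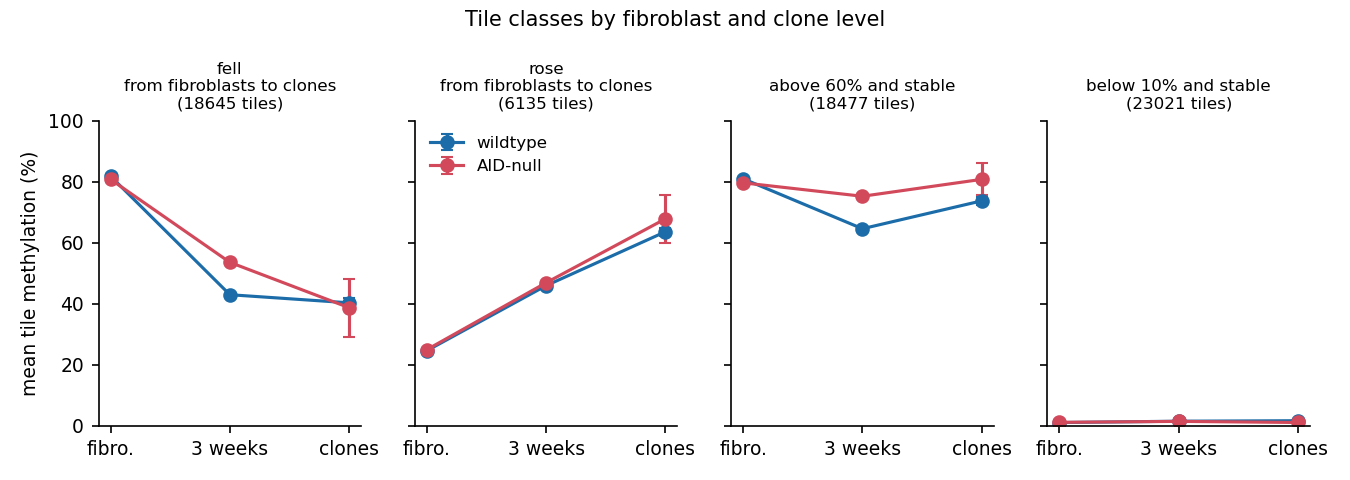
Mean methylation in percent of 4 classes of 1000 bp tiles in fibroblasts, 3-week cultures and clones of each genotype, with 1 library per genotype for the first 2 states and the mean and SD of 3 clones. Tiles that stayed above 60% stood at 64.6% in the wildtype and 75.2% in the AID-null 3-week culture, and tiles below 10% at 1.46% and 1.40%.

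Clones were compared to ask whether reprogrammed colonies differed in methylation between genotypes. No tile was called by the quasi-binomial model, with 0 higher and 0 lower of 113450 in clones labelled AID-null. At an unadjusted p under 0.05 the model gave 17647 tiles, or 15.6%. Splits of the same clones that mixed the genotypes gave up to 12384 tiles. Simulated data with no difference gave 5.19%, but had no shift of a whole clone. That share is therefore no baseline for the real clones. The tools limma, limma on median-centred ratios, edgeR and the fit with clone number as a block also called 0, with 14848, 23030, 13979 and 16430 tiles at unadjusted p under 0.05. Relative to the other autosomes, chromosome 1 had 1.25 times the coverage of the other clones in AID-null clone 1, and without chromosome 1 the model also called 0 tiles. Without AID-null clone 3, 366 tiles were called higher and 1606 lower. That clone was the most methylated, with a mean tile methylation of 54.1% against 46.9% and 42.8% in AID-null clones 1 and 2 and 44.1%, 45.8% and 46.2% in wildtype clones 1 to 3.

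**Figure D3:**
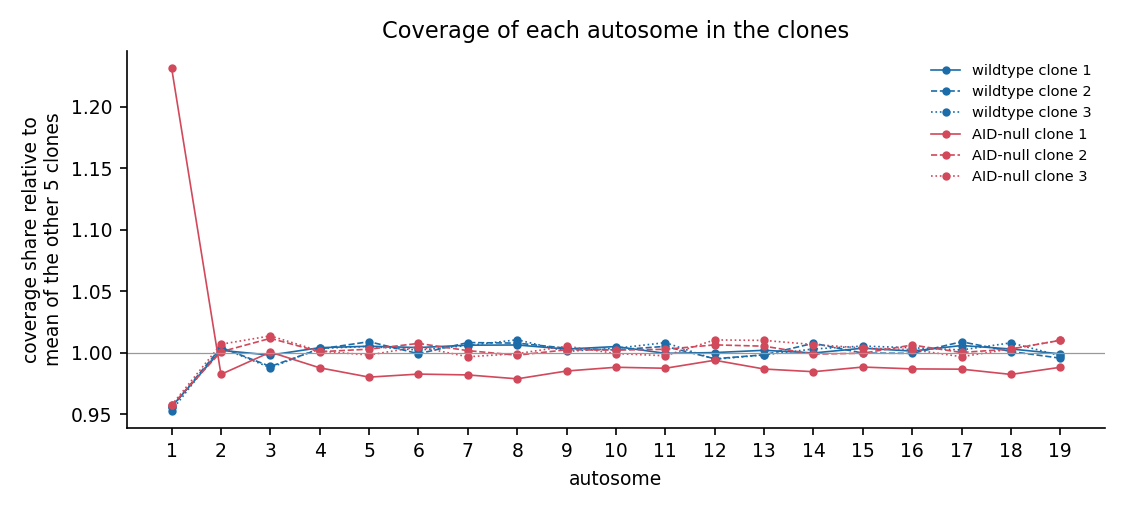
Share of total coverage on each autosome in each of the 6 clones, as a ratio to the mean of the other 5 clones. Chromosome 1 of AID-null clone 1 stood at 1.23, and all other clones and autosomes stood between 0.953 and 1.01.

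Mean levels of the clones did not separate the genotypes. Methylated reads made up 23.0% ± 2.02 in clones labelled AID-null and 23.6% ± 0.573 in wildtype clones (SD, n = 3 each, exact permutation p = 0.6). Their difference of −0.610 points changed sign when positions were weighted equally, to 1.38. Intermediate positions, between 20% and 80% methylated, made up 22.1% ± 2.11 of positions in AID-null and 30.3% ± 1.07 in wildtype clones (n = 3 each, exact permutation p = 0.1, the smallest possible). Positions at or above 80% made up 15.5% ± 4.44 and 8.95% ± 1.08 (n = 3 each, exact permutation p = 0.1). Tiles that stayed above 60% averaged 80.8% ± 5.28 in AID-null and 73.7% ± 1.30 in wildtype clones (n = 3 each, exact permutation p = 0.1). The other tile classes did not separate the genotypes. Tiles lower in clones than in fibroblasts averaged 38.7% ± 9.53 and 40.3% ± 1.62 (n = 3 each, exact permutation p = 0.8), tiles higher in clones 67.8% ± 7.79 and 63.6% ± 1.25 (p = 0.5), and tiles below 10% averaged 1.04% ± 0.481 and 1.62% ± 0.118 (p = 0.2). In the third of tiles with the fewest CpG positions the clones averaged 62.2% ± 6.79 and 57.9% ± 1.31 (n = 3 each, exact permutation p = 0.5), and in the third with the most 23.6% ± 3.57 and 23.5% ± 0.75 (n = 3 each, exact permutation p = 0.9).

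**Figure D4:**
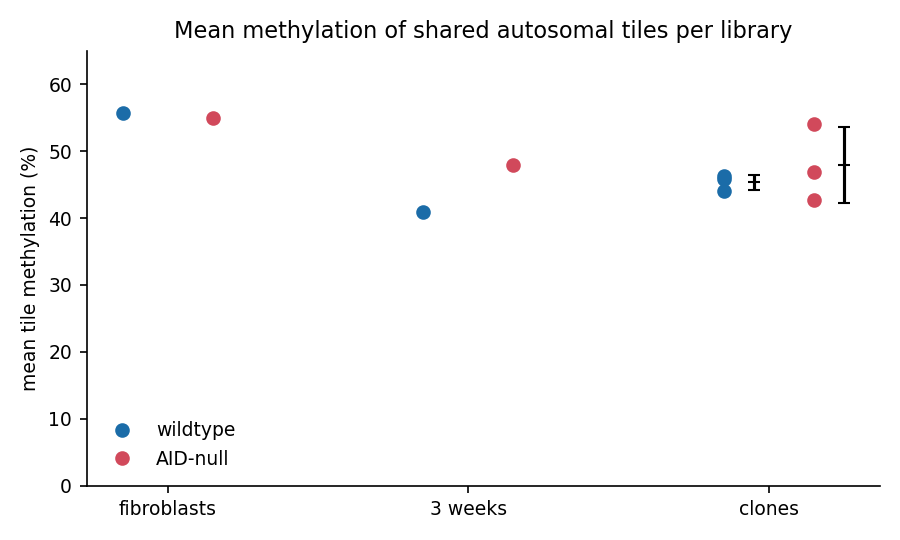
Mean methylation in percent over 108306 autosomal tiles for each of 10 RRBS libraries, with 1 library per genotype for fibroblasts and 3-week cultures and 3 clones per genotype with their mean and SD. Fibroblasts stood at 55.6% and 54.9%, wildtype clones at 44.1% to 46.2% and AID-null clones at 42.8% to 54.1%.

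Fibroblast memory, meaning methylation of fibroblasts that remains in reprogrammed cells, was compared over 1965 to 2166 tiles. These were at 70% or more in both fibroblast libraries and at 30% or less in 2 wildtype clones, and were measured in the clones kept out of the choice. Kept-out wildtype clones averaged 18.4% ± 1.61 and AID-null clones 17.0% ± 6.79 (n = 3 each, exact permutation p = 0.9). The AID-null clones averaged lower by −1.37 points, which is under their spread. Without AID-null clone 2 the difference was 1.18, and without AID-null clone 3 it was −5.22. In the same tiles the 3-week cultures stood at 29.6% to 30.6% in the wildtype and 40.9% to 41.8% in the AID-null libraries. Methylation at the secondary pluripotency genes themselves was not analysed here.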

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

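The tests in this part were chosen only after the results they weigh were seen, except the test of other splits of the clones.

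The 3-week library labelled AID-null was more methylated than the one labelled wildtype over tiles that were lower in clones, 53.6% against 43.0%, and over tiles above 60%, 75.2% against 64.6%. Unchanged fibroblasts left in the culture would need a share of 28.1% to account for the former, while the 10 fibroblast list genes most abundant in AID-null fibroblasts stood at a median of 7.19% of their fibroblast level (3.29% to 107%), 6 of them at a level at least 2 times smaller than that share. An earlier test on all 32 list genes gave a median of 30.4% (3.29% to 139%), with a standard error of 7.98 that treats genes as independent. That median was close to the share, but the 2 are unlike measures. The share was taken net of the wildtype culture, and the RNA levels were not. In the wildtype culture the same genes stood at 0.604% (Col1a1) to 89.8% (Tgfb1) of their fibroblast level. The test on abundant genes was also chosen after the earlier test, so the RNA values do not decide. Tiles higher in clones stood at 24.9% in AID-null fibroblasts, so unchanged fibroblasts would lower them in the culture. They stood at 46.9% in the AID-null and 45.9% in the wildtype culture. If the other cells matched the wildtype culture, these tiles argue against wholly unchanged fibroblasts as the whole source. Partly reprogrammed cells that kept some fibroblast transcripts may contribute. Incomplete bisulfite conversion in the AID-null library is argued against by tiles below 10%, which differed by −0.0598 points. Sex of the cells stays open, since clones labelled AID-null averaged 7.05 points more over tiles above 60% (n = 3 each, exact permutation p = 0.1), but not over tiles that were lower in clones (38.7% against 40.3%, n = 3 each, exact permutation p = 0.8), and all AID-null libraries carried Y sequence, so sex and genotype cannot be told apart, and an effect of genotype was not tested with 1 library each.

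X-linked genes were higher at 3 weeks than in fibroblasts in the libraries labelled wildtype, with a median log2 difference of 0.36 over 350 genes against 0.03 for autosomal genes. A property of X-linked genes common to all reprogrammed cells is argued against, since the X median minus the autosome median was −0.0023 in the libraries labelled AID-null. A candidate explanation is use of the second X chromosome in XX wildtype cells: the change in methylated reads on X minus that on autosomes was −15.7 points there, against −1.63 points in the AID-null libraries, and −6.65 against −0.76 points over tile means. Xist stood at 456 FPKM in wildtype fibroblasts and 149 FPKM at 3 weeks, while X kept 1.96% of coverage at 3 weeks against 2.09% in fibroblasts. This is a hypothesis from single libraries, and genotype and sex move together in it.

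The clone comparison gave 0 called tiles, and the highest of the other splits of the 6 clones also gave 0. With 10 splits in all, no share under 0.05 can be had. At an unadjusted p under 0.05 the real split had 17647 tiles and the highest other 12384.

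Y chromosome positions, kept only in the alternatives with X and Y, numbered at least 506 in each library labelled AID-null and at most 48 in each labelled wildtype. Chromosome 1 of AID-null clone 1 had 1.25 times the coverage of the other clones relative to the other autosomes, and 1.22 to 1.28 times in each of 20 windows of 10 Mb. Among genes with at least 5 FPKM in some library, 35 were at least 2-fold lower at 3 weeks in the wildtype and at least 2-fold higher in the AID-null comparison, a difference that was not tested. The opposite held for 23 genes, and this was not tested either. The AID-null change minus the wildtype change was 8.10 for Rarres2, 8.09 for Ugt1a9 and 6.77 for the pseudogene Rpl34-ps1, none of them tested. It was −5.25 for the cartilage collagen gene Col2a1, −5.13 for R3hdml and −4.76 for the pseudogene Atp6v0c-ps2, again not tested. Ugt1a9 stood at 33.1 FPKM in wildtype and 0 in AID-null fibroblasts, while Ugt1a1 stood at 0 and 33.4 FPKM. At 3 weeks Ugt1a9 stood at 0 and 6.97 FPKM, and Ugt1a1 at 0.24 and 0.32 FPKM. The Ugt1a9 value therefore rests largely on fibroblast values that were opposite in Ugt1a1, and the cause was not tested.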

How the results depend on the processing

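Of the alternatives below, restricting the clone test to tiles able to reach 25 points, the fit without the dispersion trend, leaving out chromosome 1, choosing memory tiles on AID-null clones and leaving out X and Y genes were chosen after the data were seen. Clone tile calls stayed at 0 higher and 0 lower under most alternatives. They were 3 and 1 over tiles able to reach 25 points, where fewer tiles were tested, 4 and 2 with tiles of 2000 bp, 4 and 0 with 5 CpG positions per tile, 0 and 1 with no coverage limit, and 1189 and 616 with Fisher's exact test on pooled reads, which has no spread between clones. Leaving out each clone in turn gave 0 to 366 higher and 0 to 1606 lower, above 0 only without AID-null clone 3. The labels do not say what a clone number shares, and deviations of same-numbered clones correlated at 0.0154, −0.0182 and 0.0488. Wildtype clones 1 and 2 correlated less with the AID-null clone of their own number than with another. With clone number as a block the calls were 0 and 0 and the mean difference −0.610 (exact sign-flip p = 0.75, smallest possible 0.25). The mean difference between clones reversed to 1.38 as a mean of positions and to 0.613 with each library on its own positions, and the cause was not tested. Without each clone in turn it ranged from −1.72 to 0.244. The memory tile difference ranged from −5.22 to 1.18 without each AID-null clone in turn. With memory tiles chosen on AID-null clones, wildtype clones averaged 4.40 points above kept-out AID-null clones.

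At 10 instead of 25 points, tiles higher and lower numbered 5560 and 8681 between fibroblasts, 38821 and 1600 between 3-week cultures, 7478 and 62272 for wildtype reprogramming, and 9496 and 40887 for AID-null reprogramming. Lower tiles between fibroblasts were 1210 with X and Y kept, which adds tiles that differ with sex, and between 3-week cultures 36 at a coverage of at least 20, and the cause of the latter was not tested. Counts of genes higher and lower moved with the threshold by construction. At 4-fold they were 113 and 30 between fibroblasts, 401 and 262 at 3 weeks, 1774 and 911 for wildtype and 1387 and 675 for AID-null reprogramming, and 400 and 384 for the difference of changes. At 1.5-fold they were 1116 and 457, then 2638 and 4141, with 4114 lower for wildtype and 4499 lower for AID-null reprogramming, and 2737 and 4502 for the difference. A pseudocount of 5 gave 206 and 49 between fibroblasts, 820 and 967 at 3 weeks, 2058 higher in AID-null reprogramming, and 851 and 1110 for the difference. A filter of 5 FPKM gave 355 and 76 between fibroblasts. Under upper-quartile and median-of-ratios scaling the 3-week medians were −0.60 and −0.58 for secondary pluripotency genes and 1.69 and 1.71 for fibroblast genes. The macrophage median of the difference of changes, 0.87, reversed to −0.13 with a pseudocount of 5, and the cause was not tested. Of 630 alternatives over list medians 529 stayed within 1 SD of matched random lists from the main median, and 100 moved by more. The sign changed in 20, of which 1 was for a list outside the random range, and 19 were for lists within it. The promoter window alternative was not run. RNA depth is unknown, so low FPKM values have no stated precision.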

Other observations

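The low-oxygen gene list was written after Car9 and Ndufa4l2 had been seen and before the values of its members were. Testing held-out clones, and naming the tiles in the last paragraph, were also chosen after results were seen.

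Car9, a carbonic anhydrase induced by low oxygen, stood at 5.40 FPKM in the 3-week library labelled wildtype and at 298 FPKM in the one labelled AID-null, and Ndufa4l2, a mitochondrial protein gene, at 27.8 and 980 FPKM. A broad low-oxygen response in the 3-week AID-null culture is a hypothesis for both. Of 24 other low-oxygen genes 22 lay above 0 and 11 were at least 2-fold higher, with a median log2 difference of 0.96 (percentile 100 of matched random lists), and 1.14 or 1.16 under other scalings. Adm, which encodes the vessel-relaxing peptide adrenomedullin, stood at 80.6 and 1401 FPKM, and Bnip3, a mitophagy gene, at 146 and 838 FPKM. In fibroblasts the median was −0.11. The values are consistent with such a response in this library, and whether it came from culture density, cell type or genotype was not tested and cannot be read from 1 library.

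Several other lists had small median differences between genotypes, in some of them over members that went both ways. Cartilage and bone genes had a median log2 difference of 0.06 in fibroblasts, with 4 of 11 members at least 2-fold higher and 1 lower, and Col2a1 at 2.83 and 77.8 FPKM. At 3 weeks their median was 0.39. Epithelial genes stood at 0 and 0.35, and primitive endoderm and trophoblast genes 0.24 and 0.24. Endothelial genes stood at 0 and 0.05, neural and Schwann cell genes at 0.07 and −0.18, and housekeeping genes at −0.07 and −0.22. Interferon response genes stood at 0.03 in fibroblasts and −0.17 at 3 weeks, the latter turning to 0.0092 and 0.03 under other scalings. Imprinted genes stood at 0 and −0.03, the latter turning to 0.10 and 0.11, with 4 of 21 members at least 2-fold higher and 4 lower at 3 weeks. Within that list Dlk1, a fetal growth regulator, stood at 4.51 FPKM in the wildtype and 46.9 FPKM in the AID-null library at 3 weeks. Senescence and p53 genes at 3 weeks stood at −0.09, turning to 0.10 and 0.12. Muscle genes stood at 0.03 at 3 weeks.

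Tiles called between 2 clones of each genotype were measured in the clones kept out. Calls appeared only when AID-null clone 3 was kept out, with 359 to 447 tiles higher and 1272 to 1945 lower. The higher tiles lay 15.9 to 16.8 points higher in AID-null clone 3 than in the kept-out wildtype clone, against 7.94 to 10.1 points over all tiles. The lower tiles differed there by 4.24, 0.646 and −1.26 points. Of the higher tiles 93.0%, 89.0% and 92.4% kept their direction, and of the lower tiles 35.7%, 48.4% and 54.2%. Set against all tiles, the higher tiles lay 6.70, 7.48 and 8.05 points above and the lower tiles at −5.87, −7.75 and −9.20 points. All tiles include those that stayed below 10%. Over tiles higher in clones than in fibroblasts, AID-null clone 3 stood at 76.3% and the wildtype clones at 62.2% to 64.5%. The distance from all tiles may therefore reflect the general level of that clone and adds no support to the calls.

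Among tiles able to reach 25 points, 4 passed the adjusted threshold of the quasi-binomial model with limma moderation (mm9 coordinates). The tile on chromosome 4 from 152616001 to 152617000 stood at 81.4% ± 1.74 in clones labelled AID-null and 39.1% ± 3.32 in wildtype clones, with 828 to 1427 reads per clone. The tile on chromosome 3 from 40928001 to 40929000 stood at 63.4% ± 7.56 and 23.4% ± 4.36, with 2266 to 2675 reads. The tile on chromosome 11 from 84759001 to 84760000 stood at 36.6% ± 9.14 and 5.18% ± 2.67, with 1454 to 2411 reads. The tile on chromosome 6 from 134401001 to 134402000 stood at 19.9% ± 14.4 and 74.3% ± 1.96, with 559 to 760 reads. With all tiles tested their adjusted p from the same model was 0.0943 to 0.118, and limma and edgeR gave at least 0.309 and 0.370. In each the 3 clones of a genotype lay on the same side (SD, n = 3 each). The tiles were chosen by the model on these same clones, which favours such agreement, so it adds no support.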
